A study of Mus musculus with 6 samples.

How the data were processed

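RNA from epidermal cells with high surface α6 integrin, isolated by flow cytometry from mouse embryos shortly before birth (E18.5), was sequenced in 6 libraries, 3 WT and 3 homozygous for Pik3ca H1047R, per the labels. RNA was extracted with a column kit and libraries were made with a standard Illumina protocol, per the labels' protocols; whether the protocol keeps the strand is not given in the sources used here. The deposited table gives FPKM per gene and library, with the lower and upper bound of an interval and a status for each value, per the file headers. The authors' FPKM values came from alignment with TopHat and quantification with Cufflinks, per the submitters' processing notes; versions and settings are not given in the sources used here. FPKM divides by transcript length and by a library total, and what scaled the libraries to each other is not given in the sources used here, so a change in a few very abundant genes can shift all others.

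The submitters' processing notes name the genome build mm9. The gene positions in the table did not bear this out: of 23315 symbols found in the GENCODE M21 annotation of GRCm38, 98.9% overlapped the gene of that name there. Positions are printed as the table gives them, with 1 added to each start, and are read as GRCm38. The table gives loci, which for some genes cover a neighbouring overlapping gene or only a part of the annotated gene.

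The table held 24354 genes, of which 6232 were at 0 FPKM in every library. A single value, that of Hnrnpd in mutant replicate 3, had the status FAIL. Rows of small RNAs (1313, under 200 bases) took between 2.31% and 11.1% of the summed FPKM of a library. No read totals were used here, so absolute depth is unknown; relative depth was estimated as the inverse of the most frequent ratio to WT replicate 1 among genes under 1 FPKM. No count test was run, since the values are not counts. The libraries of each group were distinct, and none of their values were pooled.

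Differential expression was tested with limma 3.58.1 in R 4.3.3 (linear model per gene, empirical Bayes with a trend in mean expression) on log2(FPKM + 1), for the 11385 genes with a mean of at least 1 FPKM over the 6 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are mutant minus WT on the log2(FPKM + 1) scale, which understates the change of low genes. Where the text gives a fold for a named gene, it is the ratio of mean FPKM. Folds used to count genes or to simulate them are on the log2(FPKM + 1) scale. Gene lists were tested with camera at its preset inter-gene correlation of 0.01, with camera at an estimated correlation, and with fry, all in limma and two-sided, with adjustment over the lists. The 41 lists (1107 distinct genes, 32 of them in more than 1 list) covered keratinocyte layers and states, the cell cycle, PI3K and its targets, metabolism, translation, stress and signalling pathways, and markers of other cell types that the sort could hold; the 38 lists with at least 5 tested members were tested. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for tables and figures. Design, lists, tests and most alternatives were fixed before the data were examined.

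Genes are named by a rule fixed at the same time: Pik3ca; the 12 genes with the largest log2 fold change in each direction among those past the threshold, with groups that do not overlap and a mean of at least 5 FPKM in the higher group, leaving out small RNA, predicted and unnamed genes; and up to 4 members of each list, those past the threshold first by smallest p and then those with the highest mean FPKM. Members of a list named only because they were few, and other genes stated to be so, were chosen after their values were seen. Some genes that the rule takes are not reported here.

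The procedure was tested on 5 simulated data sets drawn around the real gene means, with residual spreads as moderated by limma's empirical Bayes step. Between 11302 and 11322 genes were tested and 200 genes changed in each. This moderation pulls the spreads of genes toward a common trend, so recovery of the most variable genes may be overstated. The procedure recovered 89.9% of genes changed 1.5-fold, 94% of those changed 2-fold and 96.1% of those changed 4-fold. Of its calls, 5.1% were genes that had not been changed. Simulated genes varied independently, few of them changed and no library was rescaled, whereas 46% of the genes tested in the data were called. The 5.1% is thus not an error rate of those calls. Alternatives covered the pseudocount, the filter on low values, the scaling of libraries, the variance prior, library weights, a block on the replicate number, leaving out each library, the threshold and the list test. After the data were seen, 4 more were added: scaling each library to the same total FPKM, leaving out small RNAs, removing trends in transcript length and GC content, and Xist as a covariate.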

Results

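RNA sequencing was used to measure gene expression in basal epidermal cells of mouse embryos shortly before birth (E18.5). The cells were isolated by flow cytometry for high surface α6 integrin, a laminin receptor subunit that anchors basal keratinocytes to the basement membrane. Libraries were made from 3 wild-type (WT) samples and from 3 samples homozygous for Pik3ca H1047R, an activating variant in the kinase domain of the catalytic subunit of phosphoinositide 3-kinase (PI3K). All samples carry the strain label C57BL6. Nothing in the labels says that the 3 samples of a group came from separate animals, so the p-values measure only the spread between these samples, which may be technical. Levels of the sex-linked genes Xist and Ddx3y, chosen after their values were seen, differed within each group, so the 3 samples of a group did not all come from the same animals, and the spread is not technical alone.

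The deposited values were FPKM (fragments per kilobase of transcript, divided by a library total) for 24354 genes per library. How that total was set is not given in the sources used here, and the number of reads behind the values is unknown. The relative depths below therefore hold only under the scaling of the deposited values. The values summed to 752768, 767148 and 656761 FPKM in the WT libraries and to 542210, 538627 and 651769 FPKM in the mutant libraries. The most frequent ratio between libraries of values under 1 FPKM, taken as the relative worth of 1 read, gave an estimated depth relative to WT replicate 1 of 0.981 and 1.15 for the other WT libraries and of 1.24, 1.24 and 1.11 for the mutant libraries. Between 11242 and 11351 genes per library reached 1 FPKM, and the deposited interval around a value had a median halfwidth of about 33% of the value in every library. Pearson's r of the log2 values, computed across genes, lay between 0.959 and 0.98 for pairs of libraries of the same group and between 0.939 and 0.953 for pairs from different groups. The first principal component held 48.3% of the variance and separated the groups, with WT scores between -29.1 and -20.4 and mutant scores between 22.1 and 28.1.

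The comparison of mutant with WT libraries asks how activation of PI3K changes gene expression in epidermal progenitor cells before birth. Mutant libraries held more mRNA of the suprabasal keratins Krt1 and Krt10, and of 13 of 25 cholesterol synthesis and 12 of 21 fatty acid synthesis genes and targets, than WT libraries. They held less mRNA of the actins Actb and Actg1, of the integrins Itgb1 and Itga5, and of 69 of 70 cytosolic ribosomal proteins. In the list of YAP and TEAD targets and partners, 13 of 21 genes were lower and 2 higher. In that of TGF-beta and BMP targets, ligands and receptors, 16 of 26 were lower and 6 higher. The lists that all these genes belong to passed in camera and lost the call with an estimated correlation (adjusted p = 0.581 to adjusted p = 0.677). The partner keratins of basal cells, Krt5 and Krt14, did not pass the test: Krt5 was at 12028 ± 155 FPKM (SD, n = 3) in WT and 11977 ± 919 (SD, n = 3) in mutant libraries, and Krt14 was at 10194 ± 440 and 8453 ± 819 FPKM (limma adjusted p = 0.247). Krt14 passed as lower without a trend in the variance prior (adjusted p = 0.0326), with library weights (0.0374) and with Xist as a covariate (0.0233), and Krt5 passed as higher when libraries were scaled to the same total (0.00282). Krt5 and Krt14, like the other genes stated to be so below, were chosen after their values were seen.

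Pik3ca itself (chromosome 3, 32436151 to 32468486, plus strand, a part of the annotated gene) was measured at 9.04 ± 0.415 FPKM (SD, n = 3) in WT and 6.65 ± 0.602 FPKM (SD, n = 3) in mutant libraries. It fell by 0.39 on the log2 scale (SE 0.0769, limma adjusted p = 0.00433). All 3 mutant values lay under all 3 WT values, and the two-sided exact permutation test gave p = 0.1, the smallest that 3 against 3 allows. Scaling each library to the same total FPKM, an alternative chosen after the data were seen, ended this call, with a log2 fold change of -0.105 (limma adjusted p = 0.586).

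Of 11385 genes tested, 5234 (46%) changed at a limma adjusted p under 0.05, with 2642 higher and 2592 lower in mutant libraries. Most changes were small on the log2(FPKM + 1) scale, where 72.9% of these genes moved by less than 1.5-fold. On that scale, 116 were higher by 2-fold or more and 283 were lower by 2-fold or more. The groups did not overlap for 6371 tested genes (56%), against 10% by chance for 3 against 3. Scaling each library to the same total FPKM raised the log2 fold change of the median gene by 0.32 and gave 5379 higher and 842 lower genes, 86.5% higher against 50.5% with the values as deposited. Directions below hold for the values as deposited, in which the median gene had a log2 fold change of 0.01.

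**Figure D1:**
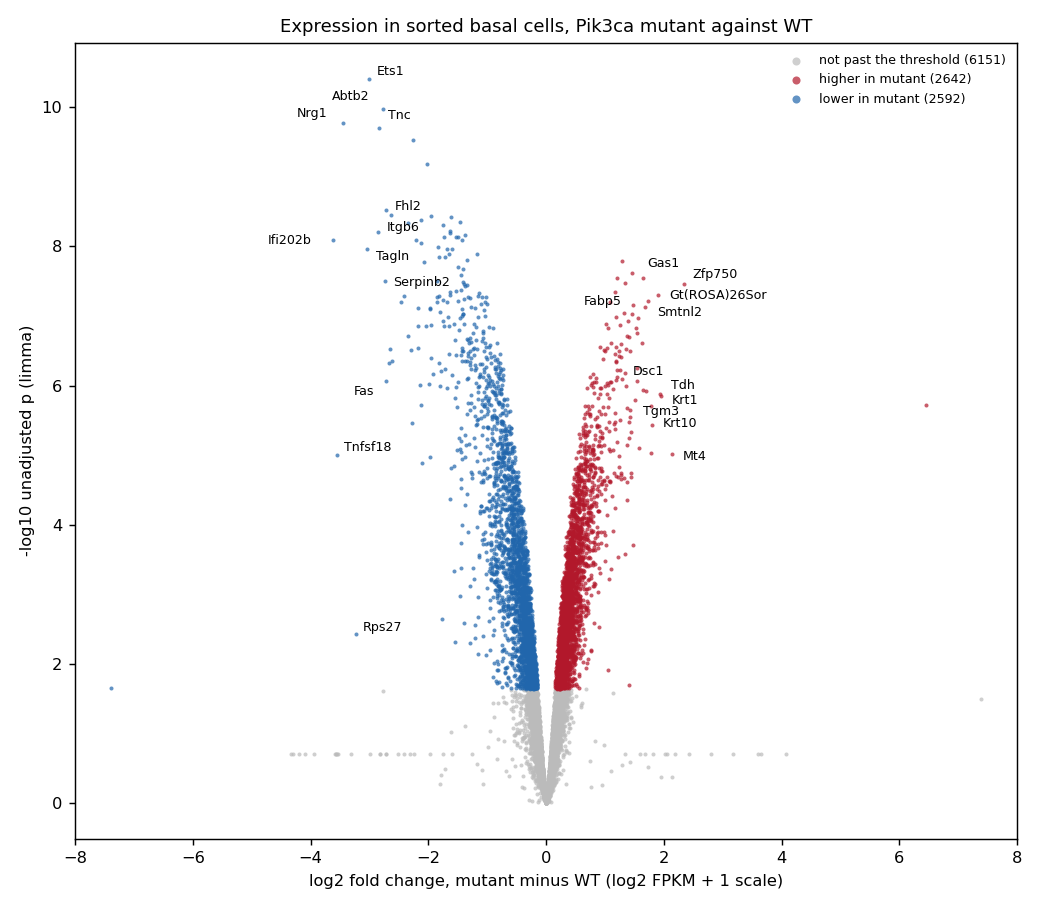
Each point is one of 11385 tested genes; the horizontal axis is the log2 fold change of mutant over WT on the log2(FPKM + 1) scale and the vertical axis is -log10 of the unadjusted limma p. Red points (2642) were higher and blue points (2592) lower in mutant libraries at an adjusted p under 0.05; the genes named are among the 12 largest changes in each direction under the naming rule.

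The 12 largest increases under the naming rule were led by Zfp750 on the log2(FPKM + 1) scale and included a pair of partner keratins. By the ratio of mean FPKM, Mt4 (5.69-fold) lay just above Zfp750 (5.61-fold). Zfp750, a transcription factor of terminal differentiation, rose from 7.53 ± 0.853 to 42.3 ± 6.24 FPKM (SD, n = 3 per group; log2 fold change 2.34, SE 0.113, limma adjusted p = 8.21e-06). Krt1 (chromosome 15, 101845426 to 101850786) rose 3.85-fold, from 1489 ± 175 to 5730 ± 666 FPKM, and its partner keratin Krt10 (chromosome 11, 99385256 to 99389364) rose 3.46-fold, from 1704 ± 222 to 5899 ± 699 FPKM. Fabp5, the epidermal fatty acid binding protein, rose from 310.3 ± 27.8 to 996 ± 16.3 FPKM. The desmosomal cadherin Dsc1 (log2 fold change 1.65), the transglutaminase Tgm3 (1.70) and the metallothionein Mt4 (2.13) rose as well. Others were Gas1 (1.65), Smtnl2 (1.74), Tdh (1.94) and the noncoding transcript Gt(ROSA)26Sor (1.90), whose exons overlap those of Thumpd3 on the other strand, so its value is uncertain. Exons of Krt10, Tdh and Gas1 also overlap those of an annotated transcript on the other strand. Reads of these may be included, as it is unknown whether the libraries keep the strand.

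Under the naming rule, which leaves out small RNA genes and genes low in both groups, the 12 largest decreases ranged from -3.62 for Ifi202b to -2.72 for Fhl2 on the log2 scale. Their order depends on the pseudocount: at 0.1, Nrg1 was at -6.323 and Ifi202b at -3.653. Tnc, the matrix protein tenascin C, fell from 144 ± 10.1 to 19.3 ± 1.0 FPKM (SD, n = 3 per group; log2 fold change -2.84, SE 0.0715, limma adjusted p = 5.71e-07). Ets1, a transcription factor gene, fell 13.4-fold from 17.6 ± 0.111 to 1.32 ± 0.061 FPKM. The growth factor gene Nrg1 (chromosome 8, 31818028 to 31918203, a part of the annotated gene) fell from 10.2 ± 0.691 to 0.031 ± 0.027 FPKM (log2 fold change -3.44). Ifi202b, an interferon-inducible gene on chromosome 1 (173962569 to 173982844), fell 12.6-fold from 507 ± 86.7 to 40.1 ± 5.75 FPKM. Serpinb2, a serine protease inhibitor, fell from 701 ± 123 to 103 ± 9.90 FPKM, and the death receptor Fas fell from 60.5 ± 7.39 to 8.55 ± 2.63 FPKM. The integrin subunit Itgb6 (-2.86), the LIM-domain gene Fhl2 (-2.72), Abtb2 (-2.78) and the cytokine Tnfsf18 (-3.55) fell too. Tagln (-3.04) is uncertain because its exons overlap those of Pcsk7 on the other strand. Exons of Tnc and Nrg1 also overlap those of an annotated transcript on the other strand. Rps27 (-3.24) is uncertain because it shares its locus with the near-identical Rps27rt, which was chosen after its values were seen and fell from 6271 to 3074 FPKM, and its WT values were 182, 15.4 and 155 FPKM. With library weights the change of Rps27 was -1.897 and its call was lost (adjusted p = 0.0547).

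**Figure D2:**
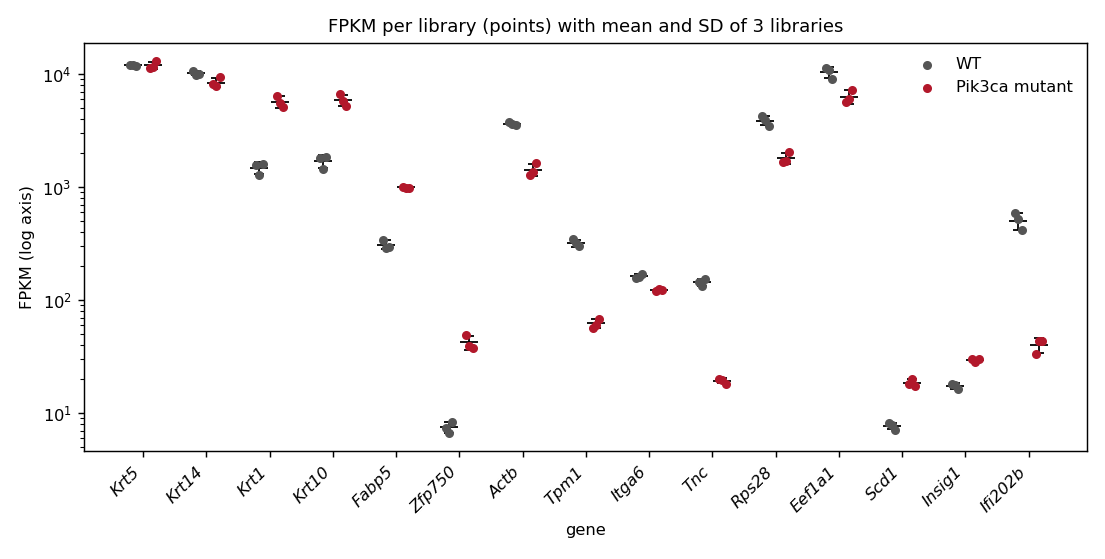
FPKM on a log axis for 15 genes; points are the 3 WT (grey) and 3 mutant (red) libraries, and bars are the mean and SD of each group. Krt1, Krt10, Fabp5, Zfp750, Scd1 and Insig1 lie higher and Actb, Tpm1, Tnc, Rps28 and Ifi202b lower in the mutant libraries, whereas the Krt5 values of the groups overlap.

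Gene lists were tested with camera at its preset inter-gene correlation of 0.01. Of 38 lists, 16 passed a Benjamini-Hochberg adjusted p under 0.05, 5 of them higher and 11 lower in mutant libraries. Splits of the 6 libraries that mix the groups passed between 9 and 14 lists in this test. With a correlation estimated within each list, 0 passed in camera (2 had an unadjusted p under 0.05), and 16 passed in fry, which tests whether the genes of a list move, on balance, one way. Only 12 lists passed in both camera and fry. Those of G2 and mitosis (fry adjusted p = 0.0582), translation factors (0.0709), dermal fibroblasts (0.0505) and oxidative phosphorylation (0.306) did not pass in fry, and those of FOXO targets (0.00338), NRF2 targets (0.0313), cell cycle inhibitors and p53 targets (0.0261) and desmosomes and tight junctions (0.0219) passed in fry alone. With libraries scaled to the same total, the medians of lists moved with the median gene. Relative to it, the medians of the 16 lists kept their sign and differed from those given below by at most 0.186. That is no separate support for the lists. The scaling multiplies all values of a library by a single factor, so little but the pseudocount could change these relative medians.

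Genes of the spinous layer, the first layer above the basal cells, rose. Of 23 measured, 15 were higher and 3 lower (15 and 3 adjusted over the list alone), with a median log2 fold change of 0.84 (camera adjusted p = 0.000321; adjusted p = 0.581 with an estimated correlation). Beside the keratins, Ptgs1 rose from 18.8 ± 0.568 to 38.9 ± 1.69 FPKM and the transcription factor Grhl3 rose from 6.13 ± 0.220 to 12.4 ± 0.222 FPKM. Among the 3 lower members were Serpinb2 and the transcription factor Ovol1 (81.1 to 27.8 FPKM), the latter chosen after its values were seen. Genes of the granular layer and cornified envelope did not pass as a list: 6 of 36 were higher and 17 lower (6 and 17 adjusted over the list alone), with a median of -0.47 (camera adjusted p = 0.0972), although they passed as lower in 5 alternatives (adjusted p = 7.95e-05 to 0.038). Tgm3, the fatty acid elongase Elovl4 (11.3 to 30.7 FPKM) and Nipal4 rose, whereas the lipoxygenase Aloxe3 fell from 3.33 ± 0.383 to 0.852 ± 0.090 FPKM. Several of the lower members belong to the Lce1 family, whose near-identical copies share reads, so their values are uncertain. Lor, an envelope protein gene chosen after its values were seen, was at 76.6 ± 24.4 FPKM in WT and 31.6 ± 15.3 FPKM in mutant libraries (limma adjusted p = 0.0155; call lost in 2 of 20 alternatives), and its groups overlapped.

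Genes of basal keratinocytes and their hemidesmosomes fell. Of 23 measured, 15 were lower and 1, Krt15, was higher (17 and 1 adjusted over the list alone), with a median of -0.41 (camera adjusted p = 4.6e-06; adjusted p = 0.581 with an estimated correlation). The median was -0.271 under quantile normalization and -0.081 when libraries were scaled to the same total (-0.397 relative to the median gene), and the list passed in both. The integrin gene Itgb1 fell from 178 ± 5.33 to 79.2 ± 2.12 FPKM, and Itga2 fell from 14 ± 0.817 to 5.54 ± 0.415 FPKM. Krt15, chosen after its values were seen, rose from 2546 ± 154 to 3586 ± 223 FPKM (limma adjusted p = 0.0153; call lost in 5 of 20 alternatives). Itga6, which encodes the integrin used for sorting and was also chosen after its values were seen, fell from 163 ± 7.55 to 123 ± 2.13 FPKM (log2 fold change -0.41). That call ended under quantile normalization (-0.16) and when libraries were scaled to the same total.

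Actin, adhesion and motility genes fell as a group. Of 31 measured, 27 were lower and 1, the metalloprotease gene Mmp2 (call lost in 5 of 20 alternatives), was higher (27 and 1 adjusted over the list alone), with a median of -0.87 (camera adjusted p = 3.85e-13; adjusted p = 0.581 with an estimated correlation). Tropomyosin 1 (Tpm1) fell from 321 ± 22.9 to 62.2 ± 5.89 FPKM, vinculin (Vcl) fell from 99.3 ± 5.06 to 31.7 ± 0.125 FPKM, and the fibronectin receptor subunit Itga5 fell from 53.4 ± 2.42 to 10.4 ± 0.378 FPKM. The cytoplasmic actins, chosen after their values were seen, fell from 3655 to 1432 FPKM for Actb and from 4915 to 1801 FPKM for Actg1. Targets of YAP and TEAD also fell, with 13 of 21 lower and 2, Dusp1 and Ajuba, higher (14 and 2 adjusted over the list alone; median -0.46, camera adjusted p = 0.000321; adjusted p = 0.581 with an estimated correlation). Tissue factor (F3) fell from 518 ± 68.7 to 113.8 ± 12.6 FPKM, Gadd45b fell from 264 to 88.1 FPKM, and Ctgf, chosen after its values were seen, fell from 211 to 54.5 FPKM. The cofactor gene Wwtr1 and the partner gene Tead4, both counted among the 13 lower, fell by 0.79 and by 1.05 on the log2 scale. Of TGF-beta and BMP targets, 16 of 26 were lower and 6 higher (16 and 7 adjusted over the list alone; median -0.37, camera adjusted p = 0.0096; adjusted p = 0.581 with an estimated correlation). Follistatin (Fst) fell from 432 ± 28.3 to 111 ± 16.7 FPKM, the BMP antagonist gene Nog fell from 5.54 to 0.68 FPKM, and the receptor gene Tgfbr2 fell from 48.1 to 23.1 FPKM. Fst and Nog encode secreted inhibitors of activin and BMP ligands. The TGF-beta and BMP list holds ligand, receptor and other pathway genes beside targets. Its 6 higher members were Tgfb2, Bmp7, Ltbp1, Tgfb3, Bmp4 and Bmpr1a.

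Several markers of other cell types were also lower in the mutant libraries, beside these adhesion and matrix genes. Of 24 dermal fibroblast markers, 12 were lower and 0 higher (12 and 0 adjusted over the list alone; median -0.55, camera adjusted p = 0.000242; adjusted p = 0.716 with an estimated correlation). Sparc fell from 310 ± 7.86 to 169.8 ± 12 FPKM and Thy1 fell from 45.4 to 21.2 FPKM, whereas Col1a1, chosen after its values were seen, was at 47.9 ± 18.4 and 32.6 ± 13.3 FPKM (limma adjusted p = 0.199). Of 9 skeletal muscle markers, 5 were lower and 1, Mybpc1, was higher (5 and 1 adjusted over the list alone; median -0.56, camera adjusted p = 0.0293; adjusted p = 0.632 with an estimated correlation); Acta1 fell from 9.07 to 2.90 FPKM. The muscle call ended with Xist as a covariate (adjusted p = 0.0534) and with length and GC trends removed (0.078). Of 6 erythroid markers, 3 were lower and 0 higher (5 and 0 adjusted over the list alone; median -0.80, camera adjusted p = 0.0932, and passing as lower in 5 alternatives), and the globin copies Hbb-b1 and Hbb-b2 among them share reads and are uncertain. Of 8 Langerhans cell, macrophage and T cell markers, 3 were lower (Cd68, Fcer1g and C1qc) and 0 higher (4 and 0 adjusted over the list alone; camera adjusted p = 0.14). These lost the call in 1, 9 and 12 of the 19 alternatives they were tested in. Of 7 adipocyte markers, 0 changed (0 adjusted over the list alone; camera adjusted p = 0.619), and Fabp4 was at 30.8, 13.2 and 2.68 FPKM in the WT libraries. Too few members were measured to test the lists of endothelial cells (3 of 3 lower: Egfl7, Sox18 and Ecscr, which lost the call in 5 of 20, 9 of 19 and 12 of 19 alternatives), melanocytes (3 of 4 lower, among them Pmel and Dct) and Merkel cells (1 of 2 higher, Krt8).

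Cytosolic ribosomal protein genes were lower almost without exception. Of 70 measured, 69 fell and 0 rose (69 and 1 adjusted over the list alone), with a median of -0.83 (camera adjusted p = 2.53e-16; adjusted p = 0.677 with an estimated correlation). The median was -0.148 under quantile normalization, where the list passed too. Rps28 fell from 3889 ± 365 to 1812 ± 202 FPKM, and Rpl37 fell from 553 ± 64.6 to 282 ± 36.0 FPKM. The one gene not called was Rpl26, at 70.3 ± 15.8 FPKM in WT and 90.5 ± 0.373 FPKM in mutant libraries. It passed as higher in 7 of 20 alternatives. All genes with a ribosomal protein name, among them some outside the list such as Rps27rt, made up 32.6%, 29.6% and 28.9% of all FPKM in the WT libraries. In the mutant libraries they made up 20.5%, 21.2% and 21.6%. Of 32 translation factor genes, 15 were lower and 3 higher (17 and 4 adjusted over the list alone; median -0.24, camera adjusted p = 0.0245; adjusted p = 0.795 with an estimated correlation). The median was 0.06 under quantile normalization, which ended the call, and 0.09 when libraries were scaled to the same total. Eif5 fell from 130.3 to 59.1 FPKM and Eif4b fell from 232 to 163 FPKM. Eef2k, the kinase that inhibits elongation factor 2, rose from 15.9 ± 0.303 to 28.4 ± 1.21 FPKM. The other higher members were Eif5b and Eif4g1, and Eef1a1, chosen like them after its values were seen, fell from 10381 to 6340 FPKM. These 3 lost the call in 5, 5 and 6 of 20 alternatives. Ribosome biogenesis genes did not pass as a list: 14 of 38 were higher, such as Ftsj3 and Ddx21, and 2, Polr1c and Npm1, were lower (14 and 2 adjusted over the list alone; median 0.12, camera adjusted p = 0.081); they passed as higher in 5 alternatives (adjusted p = 0.0027 to 0.0469). Of 43 nuclear genes of oxidative phosphorylation, 7 were lower and 0 higher (5 and 0 adjusted over the list alone; median -0.17, camera adjusted p = 0.0293; adjusted p = 0.833 with an estimated correlation), among them Cox7c and Cox4i1. The median turned to 0.12 under quantile normalization and 0.16 when libraries were scaled to the same total, each of which ended the call, as did removing length and GC trends (median -0.053, adjusted p = 0.448).

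Genes of lipid synthesis rose. Of 25 cholesterol synthesis genes and targets of SREBP2, the transcription factor that controls them, 13 were higher and 3 lower (14 and 3 adjusted over the list alone; median 0.22, or 0.391 under quantile normalization; camera adjusted p = 0.000635; adjusted p = 0.603 with an estimated correlation). Insig1, Dhcr7 and Lss rose 1.70-fold, 1.70-fold and 1.66-fold. Among the 3 lower members were Srebf2 and Cyp51, chosen after their values were seen. They lost the call in 6 and 8 of 20 alternatives. Of 21 fatty acid synthesis genes and SREBP1 targets, 12 were higher and 2, Elovl1 and Acsl3, were lower (12 and 2 adjusted over the list alone; median 0.36, camera adjusted p = 0.0031; adjusted p = 0.581 with an estimated correlation). Acsl3 lost the call in 9 of 20 alternatives. The desaturase genes Scd1 and Scd2 rose 2.40-fold and 2.08-fold, the latter from 60.0 ± 3.15 to 125 ± 10.2 FPKM. Acsl1 and Elovl6 rose 2.47-fold and 2.38-fold, and fatty acid synthase (Fasn), chosen after its values were seen, rose from 22.1 to 34.3 FPKM.

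The list of mitotic genes passed as higher in camera, by a small amount, with 17 of its 34 genes not called. Of 34 genes of G2 and mitosis, 16 were higher and 1, Anln, was lower (16 and 1 adjusted over the list alone; median 0.17, or 0.106 without mutant replicate 3; camera adjusted p = 0.0031; adjusted p = 0.795 with an estimated correlation; fry adjusted p = 0.0582). Plk1 rose from 21.5 ± 0.870 to 34.5 ± 2.79 FPKM, Ccnb1 rose from 45.9 to 64.1 FPKM and Cenpf rose 1.60-fold, whereas Mki67, chosen after its values were seen, rose from 40.1 to 48.9 FPKM (limma adjusted p = 0.037). That call was lost in 6 of 20 alternatives, among them 4 of the 6 that leave out a library (adjusted p = 0.0793 to 0.131). Genes of S phase and DNA replication did not pass as a list: 3 of 34 were higher (Ccne1, E2f2 and Fen1) and 5 lower, among them Cdt1 and Cdc45 (3 and 3 adjusted over the list alone; camera adjusted p = 0.25).

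**Figure D3:**
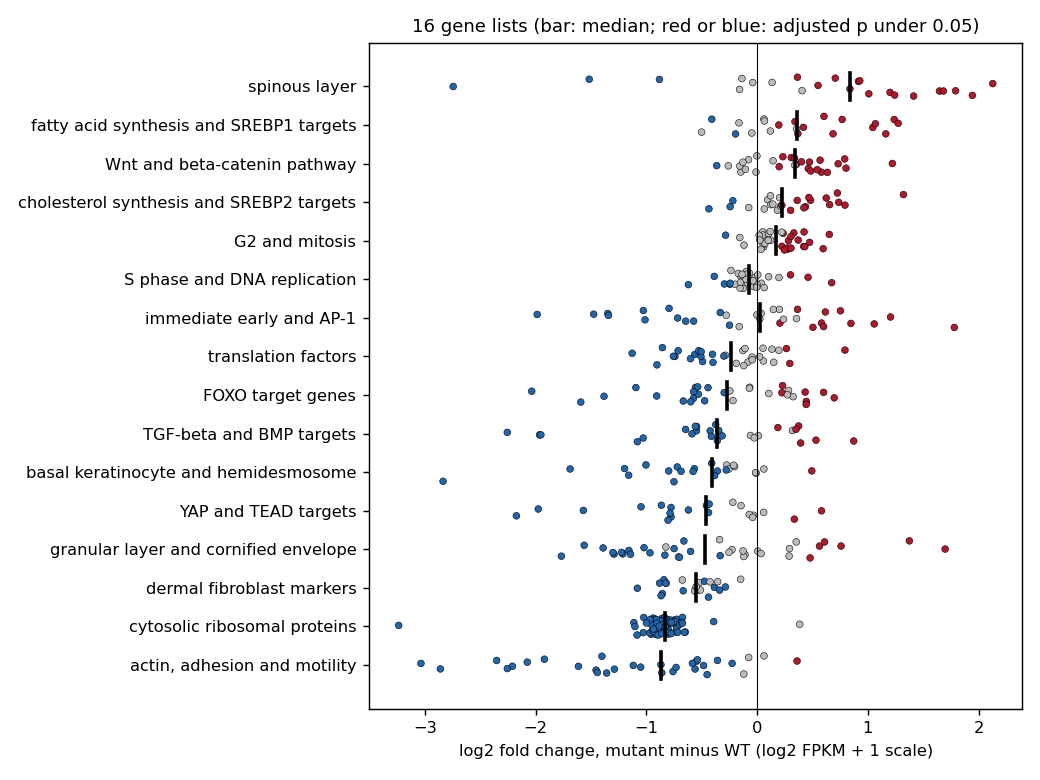
Log2 fold changes (mutant minus WT, log2(FPKM + 1) scale) of the tested members of 16 of the gene lists, one point per gene and a bar at the median. Red and blue points passed an adjusted p under 0.05; 69 of 70 ribosomal protein genes and 27 of 31 actin, adhesion and motility genes are blue, and 15 of 23 spinous genes are red. The medians of the S phase and translation factor lists turn positive when libraries are scaled to the same total, the latter also under quantile normalization.

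The list of Wnt pathway genes passed as higher in camera. Those of ERK feedback and EGFR ligands and of autophagy and lysosomes passed as lower, with members called in both directions. Of 28 Wnt and beta-catenin genes, 17 were higher and 1, Wls, was lower (18 and 1 adjusted over the list alone; median 0.34, camera adjusted p = 0.00576; adjusted p = 0.677 with an estimated correlation). The receptor genes Fzd6 and Fzd10 rose from 14.1 ± 1.06 to 25.4 ± 1.91 FPKM and from 46.4 ± 4.38 to 80.8 ± 3.04 FPKM, and the ligand gene Wnt7a rose 1.62-fold. Of 21 genes of ERK feedback and EGFR ligands, 10 were lower and 4 higher (10 and 4 adjusted over the list alone; median -0.26, camera adjusted p = 0.0322; adjusted p = 0.603 with an estimated correlation). The median was 0.03 when libraries were scaled to the same total. That call ended with library weights (adjusted p = 0.0878) and with a filter at 5 FPKM (0.108). The feedback inhibitor gene Errfi1 fell from 268 ± 14.3 to 102 ± 11.8 FPKM, the receptor gene Egfr fell from 39.6 to 24.3 FPKM and the ligand gene Epgn fell from 115 to 37.4 FPKM. Of 37 autophagy and lysosome genes, 14 were lower and 4 higher (14 and 4 adjusted over the list alone; median -0.10, camera adjusted p = 0.0373; adjusted p = 0.677 with an estimated correlation). The median was 0.19 when libraries were scaled to the same total, which ended the call, as did quantile normalization (adjusted p = 0.082). Gabarapl1 fell from 85.7 ± 4.63 to 32.3 ± 1.80 FPKM, and Atg14 and Ctsl fell by 0.66 and by 0.94 on the log2 scale.

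Genes close to PI3K signalling moved in both directions. Of 30 target genes of FOXO, the transcription factors that AKT inactivates, 15 were lower and 7 higher (15 and 9 adjusted over the list alone; median -0.27, camera adjusted p = 0.0509). With libraries scaled to the same total, 11 were higher and 7 lower, with a median of -0.011, or -0.327 relative to the median gene (camera adjusted p = 0.00171). Cited2 fell from 106 ± 2.59 to 25.3 ± 4.56 FPKM, Bcl6 fell from 39.9 ± 0.721 to 12.6 ± 0.978 FPKM and the insulin receptor substrate gene Irs2 fell from 41.4 ± 6.58 to 18.7 ± 0.366 FPKM. Of 28 genes that encode components of the PI3K pathway, 9 were higher and 8 lower (10 and 8 adjusted over the list alone; median -0.03, mean 0.07, camera adjusted p = 0.74). Pik3r3, a regulatory subunit gene, rose from 2.51 ± 0.209 to 8.06 ± 0.654 FPKM. Pik3cb and Sgk1 fell 1.74-fold and 1.73-fold.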

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

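The counts of changed genes and lists and the Pik3ca level kept their direction and their side of the threshold, or stayed within 1.5 times the reported count, under every alternative run, with 3 exceptions. Asking also for a fold of at least 1.5 left 1416 of 5234 genes, by construction. Estimating the correlation within each list left 0 of 16 lists in camera, where 2 had an unadjusted p under 0.05. Scaling each library to the same total FPKM, chosen after the data were seen, left Pik3ca at -0.105 (limma adjusted p = 0.586), against adjusted p between 0.000684 and 0.0227 under its other alternatives; this scaling moved the median gene up by 0.32. It also changed the sign of Krt5 (0.32, adjusted p = 0.00282), Srebf2 (0.11), Cyp51 (0.081), Acsl3 (0.11), Anln (0.036) and Foxn1 (0.061), of which only Krt5 passed the threshold there. Of the other genes that the naming rule takes or that are named besides it, 27 lost their call there; those printed in the text are Cdc45, Eif4b, Egfl7, Sox18, Ecscr, Cd68, Fcer1g, C1qc, Pmel, Dct, Itga6, Wls, Elovl1, Npm1, Sh3rf1 and Krt25. The oxidative phosphorylation median changed sign to 0.16 there, with the shift of all genes (-0.156 relative to the median gene), and to 0.12 under quantile normalization. Gene counts lay between 3798 and 7088 under the other alternatives, and between 66.5% and 99.8% of the genes called in the reported result kept their call and direction, except that 4 changed direction under quantile normalization.

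Leaving out each library in turn gave between 3866 and 5081 genes, between 14 and 19 lists and a Pik3ca change between -0.44 and -0.33. Lists of translation factors, oxidative phosphorylation, autophagy and ERK feedback each lost their call without at least 1 library: translation factors without WT replicate 1 (adjusted p = 0.0508), and oxidative phosphorylation without WT replicate 1 or 2 or mutant replicate 1 or 2 (0.0614 to 0.141). Autophagy lost it without WT replicate 1 (0.0508) or mutant replicate 2 (0.0505), and ERK feedback without WT replicate 3 (0.0574). Other alternatives that ended a list's call were quantile normalization for translation factors (0.919), oxidative phosphorylation (0.0568) and autophagy (0.082), scaling to the same total for oxidative phosphorylation (0.682) and autophagy (0.116), removed length and GC trends for oxidative phosphorylation (0.448), library weights (0.0878) and a filter at 5 FPKM (0.108) for ERK feedback, and Xist as a covariate (0.0534) and removed length and GC trends (0.078) for muscle markers. Without a library, medians that moved by over 1.5 times were those of G2 and mitosis (0.106 without mutant replicate 3), muscle markers (-0.341 without WT replicate 1) and oxidative phosphorylation (-0.098 without mutant replicate 1). Muscle markers also moved to -0.891 at a pseudocount of 0.1 and to -0.255 with no filter, oxidative phosphorylation to -0.264 with library weights and -0.11 with Xist as a covariate, and autophagy to -0.158 with a filter at 5 FPKM and -0.163 with removed length and GC trends. The FOXO list, just over the threshold as reported, passed it in 13 alternatives. Other lists that did not pass as reported did so in some alternatives: hair follicle genes in 6, granular genes, ribosome biogenesis genes and erythroid markers in 5 each, interferon response genes in 2, and NRF2 targets and Langerhans cell, macrophage and T cell markers in 1 each. Of 213 genes besides Pik3ca that the naming rule takes or that are named outside it, 183 were tested in 20 alternatives and 30 in 19, mostly for lack of a mean of 5 FPKM; 160 kept their call in each one they were tested in. Without at least 1 library, 26 lost it. Those printed in the text are Foxn1 (without each of the 6 libraries in turn), Acsl3, C1qc, Cyp51, Ecscr, Fcer1g and Sox18 (5 libraries each), Dct, Eef1a1, Eif4g1, Eif5b, Krt8, Mki67 and Mmp2 (4 each), Ajuba, Egfl7, Krt15 and Srebf2 (3 each), Hbb-b2, Lor and Mybpc1 (2 each), and Krt25 and Npm1 (1 each).

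The replicate numbers were not taken to pair the samples. Deviations from the group means correlated across genes at 0.127, 0.122 and -0.007 for equal numbers, and each of the first 2 numbers correlated best with its own number but the last did not. The fit with the replicate block gave 3798 genes (1889 higher, 1909 lower), 19 lists and a Pik3ca change of -0.395 (limma adjusted p = 0.0227). The depth in reads is unknown, and the fold changes of genes near 1 FPKM depend on the pseudocount.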

Other observations

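Further gene lists did not pass as a whole, although many of their members changed. Of 26 hair follicle genes, 13 were higher and 3 lower (13 and 3 adjusted over the list alone; median 0.29, camera adjusted p = 0.0534, and passing as higher in 6 alternatives with adjusted p = 0.0136 to 0.0454). Dlx3 rose from 3.34 to 8.88 FPKM, Shh from 3.10 to 6.72 FPKM and Lhx2 from 9.82 to 17.2 FPKM, and the Hedgehog receptor gene Ptch1, chosen after its values were seen, rose from 45.6 to 76.5 FPKM, whereas Sox9, Krt25 and Foxn1 fell, the last with a call lost in 10 of 20 alternatives, among them each of the 6 that leave out a library. Of 15 Notch pathway genes, 6 were higher and 4 lower (6 and 4 adjusted over the list alone; camera adjusted p = 0.289): Nrarp rose from 14 to 34.4 FPKM and Notch3 from 6.68 to 17.3 FPKM, and the ligand gene Jag1 fell from 52.3 to 27.5 FPKM. Of 19 JNK pathway genes, 9 were lower and 3 higher (9 and 4 adjusted over the list alone; median -0.17, or 0.14 with libraries scaled to the same total; camera adjusted p = 0.337). Map2k4 fell from 31.4 to 19.5 FPKM, and the scaffold gene Sh3rf1, chosen after its values were seen, fell from 10.2 to 7.85 FPKM. Immediate early genes split, with 11 of 32 higher and 12 lower (13 and 13 adjusted over the list alone; median 0.03, mean -0.08, camera adjusted p = 0.815). Egr1 rose from 375 to 870 FPKM and Fos from 379 to 681 FPKM, both chosen after their values were seen, whereas Ier3 fell from 243 to 86.3 FPKM, Maff from 95.8 to 37.0 FPKM and Hspa1a, which shares reads with Hspa1b and is uncertain, from 68.9 to 17.0 FPKM. Of 15 interferon response genes, 7 were lower and 3 higher (7 and 3 adjusted over the list alone; median -0.17, or 0.06 with libraries scaled to the same total; camera adjusted p = 0.153), and Gbp2 fell from 4.98 to 0.165 FPKM. Of 14 stress and wound genes, 6 were higher and 6 lower (7 and 6 adjusted over the list alone; camera adjusted p = 0.815), and the urokinase receptor gene Plaur fell from 57.5 to 8.42 FPKM.

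Junction and metabolic genes also went both ways. Of 22 desmosome and tight junction genes, 10 were higher and 7 lower (10 and 8 adjusted over the list alone; median 0.04, mean -0.05, camera adjusted p = 0.997): Cldn1 fell from 195.7 to 76.2 FPKM, and Tjp3 rose from 2.69 to 5.80 FPKM. Of 32 glycolysis and HIF1 targets, 13 were lower and 6 higher (13 and 6 adjusted over the list alone; camera adjusted p = 0.176). Of 25 genes of the pentose phosphate pathway and nucleotide synthesis, 9 were higher and 5 lower (9 and 5 adjusted over the list alone; median 0.09, mean -0.04, camera adjusted p = 0.61), with Pgd and G6pdx up 1.61-fold each and Ctps down from 118 to 36.4 FPKM. Of 28 ATF4 targets, 8 were higher and 7 lower (8 and 7 adjusted over the list alone; median 0.04, mean -0.06, camera adjusted p = 0.815), and Atf4 fell from 316 to 174 FPKM. Of 20 genes of the unfolded protein response, 8 were higher and 5 lower (8 and 5 adjusted over the list alone; camera adjusted p = 0.509), and Xbp1 fell from 54.6 to 31.6 FPKM. Of 22 NRF2 targets, 8 were higher and 3 lower (8 and 3 adjusted over the list alone; camera adjusted p = 0.14), of 22 cell cycle inhibitors and p53 targets 8 were higher and 6 lower (8 and 6 adjusted over the list alone; median 0.00, mean -0.05, camera adjusted p = 0.711), and of 7 periderm genes 3 were higher and 2 lower (3 and 2 adjusted over the list alone; camera adjusted p = 0.509).

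The libraries differed in sex-linked genes. Xist was at 30.5, 24.2 and 0.53 FPKM in the WT libraries and at 0.73, 0.05 and 71.1 FPKM in the mutant libraries, and the Y-linked Ddx3y was at 15.8, 17.6 and 20.9 FPKM and at 19.8, 22.7 and 0.21 FPKM. WT replicates 1 and 2 thus held transcripts of both kinds. With Xist as a covariate, 6127 genes passed, and without mutant replicate 3, 5081 did.

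Of the tests that follow, those on other transcripts with a 5' terminal oligopyrimidine tract and on layers of suprabasal cells were chosen after the results were seen; the others were written before. The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 5234 genes and the highest other split 3, so 1 of 10 splits gave as many. For lists in camera the real split gave 16 and the other splits between 9 and 14, so again 1 of 10 gave as many. The number of lists in camera thus hardly sets the real split apart. In fry the other splits gave 0. Of the 16 lists, 3 had a larger median, in either direction, in another split: dermal fibroblast markers (0.642 against -0.549), translation factors (0.246 against -0.237) and oxidative phosphorylation (0.247 against -0.171).

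Ribosomal protein genes fell together, by a median of -0.83. Transcript length and GC content were those of the longest annotated transcript of each gene. A bias by these measures is argued against: 319 other genes matched to the ribosomal protein genes on both had a median of -0.078 (95% interval -0.11 to -0.05). This lay above the bound of -0.42 set in advance. The median length so measured was 1100 bases for the ribosomal protein genes and 1117 for the matched genes. The transcripts expressed can be shorter, so a bias by their length stays open. Of 23 other genes whose mRNAs carry a 5' terminal oligopyrimidine tract, 20 were lower and 0 higher, with a median of -0.53 (95% interval -0.71 to -0.44) against -0.01 for matched genes (one-sided permutation p = 3e-04). Both intervals and the permutation p come from resampling genes, not libraries, and so treat genes that move together as independent. The estimated correlation within the ribosomal protein list was 0.909. The genes were not matched on abundance. A change shared by this class of mRNA therefore stays a hypothesis, and 10 of the 23 are also in the translation factor list. Whether the mutation acts on their transcription or stability was not tested, and the scaling between libraries stays open as a source of part of the size, since the median was -0.15 under quantile normalization and -0.50 with libraries scaled to the same total.

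Spinous genes rose, by 0.82 for the median member (95% interval across libraries 0.68 to 0.95). More suprabasal cells of all layers in the sorted gate would raise granular genes too, and are argued against as the whole cause. The median granular member changed by -0.5 (-1.15 to 0.15), a difference of 1.31 (0.64 to 1.99). Granular genes went both ways, with 6 higher and 17 lower, and several of the lower are Lce1 copies with uncertain values. Their library scores overlapped, at -0.377 in WT replicate 2 and -0.242 in mutant replicate 3. Whether the granular genes fell stays open: the list passed as lower in 5 alternatives, among them those without WT replicate 2 (median -0.677, adjusted p = 0.00527) and without mutant replicate 3 (-0.648, 0.038), while another split of the libraries gave it a median of 0.489 in size, against -0.47. More spinous cells alone may account for part of the rise: 15 called basal genes were lower and 1 higher, and the design cannot tell such cells from basal cells that express spinous genes. How far the sort for α6 integrin removed spinous cells is not given in the sources used here. WT libraries already held Krt1 at 1489 ± 175 FPKM. Single basal genes do not decide: Krt5 was at a log2 fold change of -0.01, Krt14 at -0.274 and Itga6 at -0.41, or at 0.32 for Krt5 and -0.081 for Itga6 with libraries scaled to the same total. A change within basal cells, which the genotype would give, stays open and untested.

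Ifi202b fell 12.6-fold, and its level is known to differ between mouse strains. Reads shared with its family are argued against: the summed FPKM of the family was 12.3-fold higher in WT libraries, and no other member gained any of the 467 FPKM that Ifi202b lost (each was lower in mutant libraries, the least so by 0.02 FPKM). A chromosome segment from another strain may still explain the fall: within 5 Mb, 1 of 48 genes (2.1%) changed by at least 2-fold, against 3.5% elsewhere (odds ratio 0.58, 95% interval 0.01 to 3.44, Fisher's exact p = 1), which is too few genes to decide. The neighbours Ifi203 and Ifi204 were lower too, at 0.98 and 0.42 FPKM in WT and 0.10 and 0.08 FPKM in mutant libraries, but both lie under the expression filter. All samples carry the strain label C57BL6, and the values do not tell in which group a segment from another strain would lie. The difference may thus be a high level in WT as much as a fall in mutant libraries. An effect of the genotype stays open.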
